A study of Danio rerio with 7 samples.

How the data were processed

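The series comprised 7 zebrafish (Danio rerio) samples, 1 per group, and the reads of 2 of them were analysed here. The first was a chromatin immunoprecipitation (ChIP) library made with an antibody against dimethylated lysine 4 of histone H3 (H3K4me2) from embryos labelled 6 hours post fertilization (hpf). The other was an ATAC library, made by transposase insertion into open chromatin, from embryos labelled 4 hpf. The name of the deposited ATAC read list gives 43 hpf instead, whose meaning was not given in the sources used here, and the stage was taken from the label. The libraries for H3K27ac in intestine and in brain, for H3K4me1 at 2.5 hpf, for H3K27me3 at 4 hpf and the input at 4 hpf were not used here. Samples were grouped by the antibody or assay and the stage or tissue in their titles.

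The authors deposited each library as a list of aligned reads with 4 columns, chromosome, start, end and strand, and with no header and no measured value. Reads were aligned with Bowtie 1.1.1, per the submitters' processing notes. The genome build, the alignment settings and any filter on the reads were not given in the sources used here. All reads were 51 bp long in both libraries. Starts counted from 1 and the listed end was the base after the read, as read from the smallest and largest mitochondrial positions, and coordinates are printed here counted from 1 with both ends included. Repeated positions were present in both deposited lists, so they had not been removed before deposit. No build was named, and no gene annotation was used here. Regions are given by position without gene names, and the positions hold only for the build of the alignment. The chromosome lengths used were the largest read coordinates of each of the 25 chromosomes, 1.36 Gb in all.

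Reads at the same 5' position and strand were counted once. The 5' end of each H3K4me2 read was moved 75 bp downstream, towards the assumed centre of its fragment, whose length was not measured. The 5' end of each ATAC read was moved by 4 bp on the plus strand and 5 bp on the minus strand, towards the centre of the transposase site, and spread over 100 bp for calling regions. Each chromosome was divided into 200 bp bins, and an ATAC read whose spread crossed a bin edge counted in both bins. ATAC regions were ranked by these counts, while the read numbers of named regions take each read once. The count in each bin was tested with a one-sided Poisson test against the larger of the genome-wide mean and the mean of the 5000 bp on either side, with Benjamini-Hochberg adjustment over bins with reads. Bins with an adjusted p under 0.01 were called and joined where they lay within 400 bp. The local background holds down the width of a called region, since a wide stretch of reads raises its own background. No input was used, so the background came from each library itself.

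Regions of the 2 libraries were said to meet where they shared at least 1 bp. The share that met was compared with 1000 circular shifts, along their chromosomes, of the regions whose share was taken, ATAC or H3K4me2. The mean H3K4me2 read density in the central 400 bp of ATAC regions was compared with 1000 such shifts of the ATAC regions. The permutation tests were one-sided, and those of the 2 shares describe the same overlap from both sides. The smallest p that 1000 shifts can give is 0.000999. The 3 tests made this way all reached that value, so adjustment over them leaves them at it. Read density is given as fold over the library's own genome-wide mean. A ratio of centre to flank set the central 100 bp of ATAC regions against the bases 200 to 400 bp away on both sides. Shares carry exact binomial (Clopper-Pearson) 95% intervals and counts exact Poisson 95% intervals, the ratios carry normal 95% intervals of their log, and Spearman's rho carries a 95% interval from 200 bootstrap draws. All of these cover counting error only, since reads are not independent molecules and neighbouring regions are not independent.

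With 1 library per group there was no replicate spread, and no test between groups was made. The tests describe these 2 libraries, which differ in both assay and stage, and not the stages or assays in general. Depth differed: 27643289 distinct nuclear reads for H3K4me2 gave a mean of 4.07 per bin, and 4361114 for ATAC gave 0.961. The ATAC mean counts a read in 2 bins where its spread crossed an edge, so the 2 means are on unlike scales. The smallest count that could be called in a bin was 14 reads for H3K4me2, 3.44-fold the mean, and 7 reads for ATAC, 7.28-fold the mean.

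Region calling was tested on simulated reads with a uniform background and 200 planted regions at each of 3 strengths per library. Each planted region filled several whole bins and counted as called if any of these bins was called. Narrower regions, or regions that cross bin edges, may be recovered less often. At the H3K4me2 depth 47.0% of regions planted at 3-fold, 98.5% at 5-fold and 100% at 10-fold were called, with 3 of 494 calls outside planted regions. At the ATAC depth 1% of regions planted at 3-fold, 11% at 5-fold and 70% at 10-fold were called, with 0 of 164 calls outside. The background of the libraries is not uniform, so these calls outside do not give the share of false calls in the data. Planting 50% of the ATAC regions inside H3K4me2 regions gave a measured share of 47.0%, against 0.588% after shifts. Shared regions were planted at the same strength in both libraries, so this does not show how well the share is recovered where strengths differ.

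The rule for the regions named in the text was fixed before the data were examined. It took the 10 regions with most reads and the 10 widest regions of each library, and the 10 widest H3K4me2 regions that met an ATAC region. Other regions named below were chosen after their values were seen, and are marked so. The planned comparisons at promoters, across 18 fixed gene lists, by annotated feature and by promoter sequence class needed an annotation of the same build and were not run. Alternatives kept all reads, used an adjusted p under 1e-05, the genome-wide background alone, 500 bp bins, H3K4me2 reads thinned to the ATAC number, coverage of 50% of a region in place of 1 bp, or left out chromosome 4. Other alternatives were chosen after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.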

Results

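Chromatin of early zebrafish embryos was profiled by H3K4me2 ChIP-seq at 6 hpf, when gastrulation begins, and by ATAC-seq at 4 hpf, in the blastula. H3K4me2 is a histone modification found at promoters and enhancers, and ATAC-seq maps open chromatin through the insertion of sequencing adapters by the Tn5 transposase. The stage of the ATAC library is that of its label; the name of its deposited read list gives 43 hpf, so each statement on openness at 4 hpf depends on the label. By its title, the series concerned the chromatin surroundings of enhancers in early development. Each group held 1 library, so no value below has a replicate error, and intervals cover counting error only. The H3K4me2 library held 30635591 reads and the ATAC library 5454421. On chromosomes 1 to 25 there were 30531385 and 4946358 reads, of which 9.46% (95% interval 9.45 to 9.47) and 11.8% (11.8 to 11.9) repeated a position already seen. No read was placed on other sequences apart from the mitochondrial genome.

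The ATAC reads carried the mark of transposase insertion and the H3K4me2 reads did not. Tn5 leaves a duplication of 9 bp at each insertion, so reads from both sides of an insertion start on opposite strands across 9 bp. In the ATAC library 122597 pairs of opposite-strand read starts spanned 9 bp, 3.57 times (3.55 to 3.59) the median of the 20 neighbouring spans. In the H3K4me2 library the ratio was 0.995 (0.992 to 0.998). H3K4me2 pairs spanning more than 20 bp were most frequent at 51 bp, the read length, at 1.19 times the number at 150 bp. No separate peak followed at longer spans, so these pairs gave no estimate of the fragment length.

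**Figure D1:**
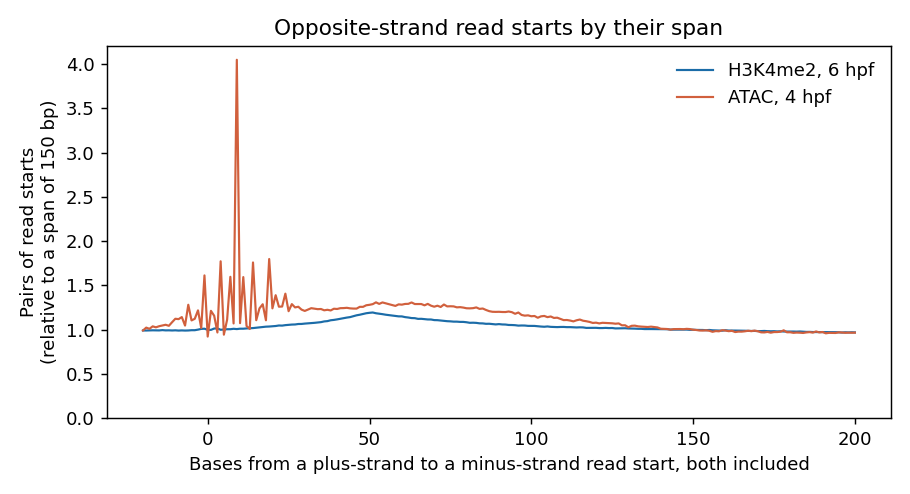
Pairs of opposite-strand read starts (vertical axis, relative to the number at a span of 150 bp) against the bases they span (horizontal axis), 1 line per library. The ATAC line peaks at 9 bp and the H3K4me2 line is flat there.

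H3K4me2 was enriched in 31023 regions and open chromatin in 47353, each covering about the same small part of the genome. H3K4me2 regions spanned 20.4 Mb, 1.502% of the summed chromosome length, and held 14.3% (14.3 to 14.3) of distinct reads, 9.52-fold the mean density. ATAC regions spanned 19.99 Mb, 1.47%, and held 27.4% (27.4 to 27.4) of distinct reads, 18.6-fold the mean. H3K4me2 regions were wider, with a median of 600 bp (quartiles 200 and 1000 bp, largest 3600 bp), against 400 bp (200 and 600 bp, largest 3000 bp) for ATAC regions. The counts depend on depth and threshold: 15720 H3K4me2 regions were called from reads thinned to the ATAC number, and 26971 ATAC regions at an adjusted p under 1e-05. The ATAC library could call only bins at 7.28-fold the mean or more, so weaker open sites were seldom detected at its depth. H3K4me2 bins could be called from 3.44-fold, and widths were not compared at equal depth, so the difference in width may depend on depth too.

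Regions marked by H3K4me2 at 6 hpf were far more often open in the ATAC library labelled 4 hpf than placement by chance would give. Of the 31023 H3K4me2 regions 17664 met an ATAC region, 56.9% (56.4 to 57.5). After 1000 circular shifts the mean share was 3.07% and the highest 3.34%, an 18.6-fold difference (permutation test, one-sided p = 0.000999, the smallest 1000 shifts can give). In the other direction 17963 of the 47353 ATAC regions met an H3K4me2 region, 37.9% (37.5 to 38.4), against a mean of 2.02% and a highest of 2.27% after shifts, 18.8-fold (one-sided permutation p = 0.000999). The remaining 29390 ATAC regions met no H3K4me2 region. With H3K4me2 reads thinned to the ATAC number, the share of ATAC regions that met an H3K4me2 region was 21.8%. The fold over shifts depended on the settings, from 10.3 with the genome-wide background to 32.8 at an adjusted p under 1e-05 for ATAC regions, and from 10.2 to 32.6 for H3K4me2 regions.

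The share that met rose with the number of reads in both sets. Among ATAC regions it was 11.8% (10.9 to 12.8) in the 10% with fewest reads, which had a median summed bin count of 7. It was 72.1% (70.8 to 73.4) in the 10% with most, which had a median summed bin count of 119. Among H3K4me2 regions it went from 9.44% (8.44 to 10.5) to 96.7% (96.0 to 97.3), so that 102 of the 3102 H3K4me2 regions in the highest 10% met no ATAC region. When 50% of the region had to be covered, the last share was 63.5%. Width followed the same order. Of 9704 H3K4me2 regions of 200 bp, 17.3% (16.6 to 18.1) met an ATAC region, against 64.5% (63.6 to 65.3) at 400 to 800 bp, 90.3% (89.6 to 91.0) at 1000 to 1400 bp and 95.4% (94.2 to 96.4) of the 1463 regions of 1600 bp or more. Wider regions also have more bases with which to meet another.

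**Figure D2:**
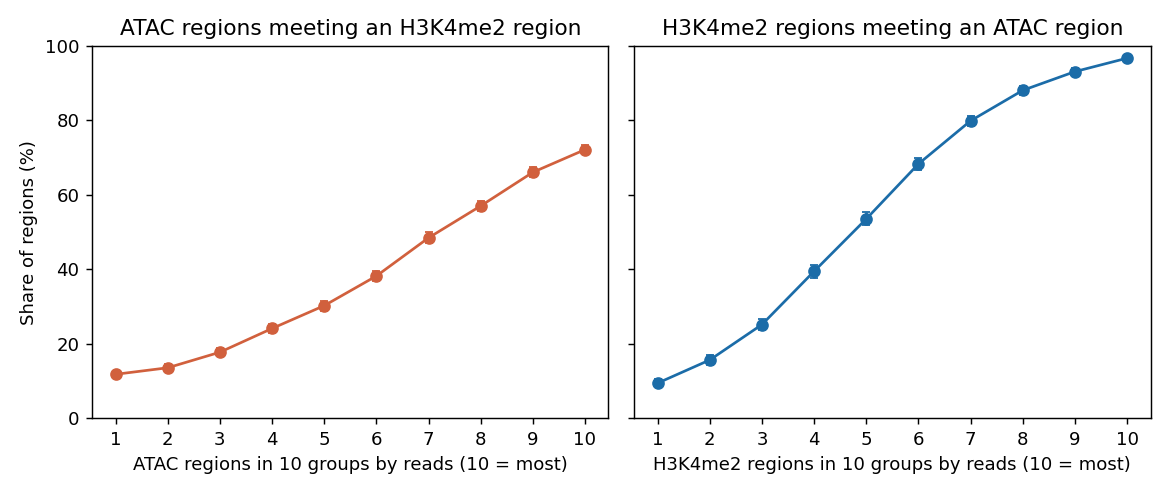
Share of regions that met a region of the other library (vertical axis, percent) by rank of the regions' reads in 10 equal groups (horizontal axis, group 10 holding most reads), for ATAC regions on the left and H3K4me2 regions on the right, with exact binomial 95% intervals as bars. The share rises from 11.8% to 72.1% for ATAC regions and from 9.44% to 96.7% for H3K4me2 regions.

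H3K4me2 reads were concentrated on the open sites themselves. In the central 400 bp of all ATAC regions their density was 4.94-fold the genome mean, against 1.01-fold after shifts with a highest of 1.03 (permutation test, one-sided p = 0.000999). It was 10.2-fold (10.1 to 10.2) at ATAC regions that met an H3K4me2 region and 1.74-fold (1.74 to 1.75) at those that did not, while the ATAC density itself was 19.0-fold (18.9 to 19.0) and 13.4-fold (13.4 to 13.5). Among the 10% of ATAC regions with most reads the order of ATAC densities was the other way: 47.1-fold (46.8 to 47.5) at the 1319 without an H3K4me2 region, where H3K4me2 was 2.55-fold, and 33.6-fold (33.4 to 33.7) at the 3416 with one, where it was 11.8-fold. These sets had median summed bin counts of 118 and 120 but median widths of 600 and 1000 bp. A higher density in the centre therefore follows at least in part from the narrower width. Between 2 and 3 kb away, ATAC was also higher around the 1319 sites, at 4.503-fold against 2.102-fold around the 3416. H3K4me2 there was 1.864-fold against 1.480-fold. Region width does not account for these levels outside the regions, and what raised them was not tested. The difference in H3K4me2 in the central 400 bp follows in part from how these sets were chosen. At ATAC regions with an H3K4me2 region, H3K4me2 fell from 10.6-fold in the central 200 bp to 4.43-fold at 550 bp from the centre and 1.35-fold between 2 and 3 kb away. The centre exceeded the flanks 200 to 400 bp away by a ratio of 1.39 (1.39 to 1.40) over all ATAC regions. Measured around ATAC summits with unmoved reads it was 1.37, but 1.0998 (1.09 to 1.11) in the 10% with most ATAC reads that met an H3K4me2 region, and 0.891 (0.866 to 0.916), with the centre below the flanks, in the 354 such sites of the 1% with most.

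**Figure D3:**
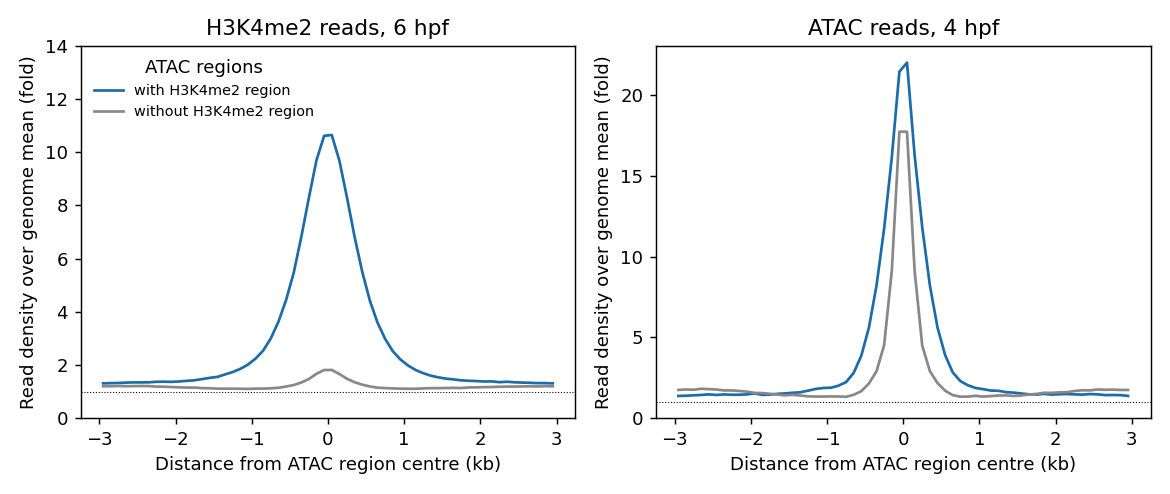
Read density over the genome mean (vertical axes, fold) against distance from the centre of ATAC regions (horizontal axes, kb), for H3K4me2 reads on the left and ATAC reads on the right, with 1 line for the 17963 ATAC regions that met an H3K4me2 region and 1 for the 29390 that did not. H3K4me2 reaches 10.6-fold in the central 200 bp of the first set and 1.81-fold in the other, while ATAC reaches 21.7-fold and 17.7-fold.

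Across the 47353 ATAC regions the ATAC and H3K4me2 reads in the central 400 bp were related, with a Spearman rho of 0.402 (0.395 to 0.409). Corrected for counting noise, from reads split at random in 2 parts, rho was 0.471 (0.463 to 0.479). Across the 31023 H3K4me2 regions rho was 0.575. These are relations across regions, which are not independent replicates.

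The H3K4me2 region with most reads lay on chromosome 4 at 7447401 to 7448600, with 1179 reads, 48.2-fold the mean, in 1200 bp and an ATAC density of 25.2-fold. With repeated reads kept its H3K4me2 density was 78.2-fold, so counting each position and strand once held its value down. What raised the reads there was not tested, and no input was used. Next came chromosome 3 at 25154601 to 25157600, with 1105 reads and 18.1-fold, chromosome 4 at 61296201 to 61299800, with 1019 reads and 13.9-fold, and chromosome 16 at 12889201 to 12891800, with 936 reads and 17.7-fold. These next regions changed less with repeated reads kept, to 19.9-fold, 15.1-fold and 19.4-fold. The 10 regions with most reads held 821 to 1179 reads and lay on 8 chromosomes. All 10 met an ATAC region, with ATAC densities of 11.2-fold to 32.3-fold.

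The 10 widest H3K4me2 regions called against the local background measured 3000 to 3600 bp. All 10 met an ATAC region too, so they were also the 10 widest with an ATAC region. Against the genome-wide background other stretches were wider, up to 15800 bp. A width of 3600 bp was reached on chromosome 4 at 61296201 to 61299800 and on chromosome 17 at 34969801 to 34973400, where H3K4me2 was 12.2-fold and ATAC 22.9-fold the mean. Widths of 3200 bp were reached on chromosome 3 at 19950601 to 19953800, with an ATAC density of 33.7-fold, and on chromosome 14 at 32018601 to 32021800, with 18.8-fold. In the 6 kb on each side of the chromosome 4 region 42 of 60 bins held no read of either library.

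**Figure D4:**
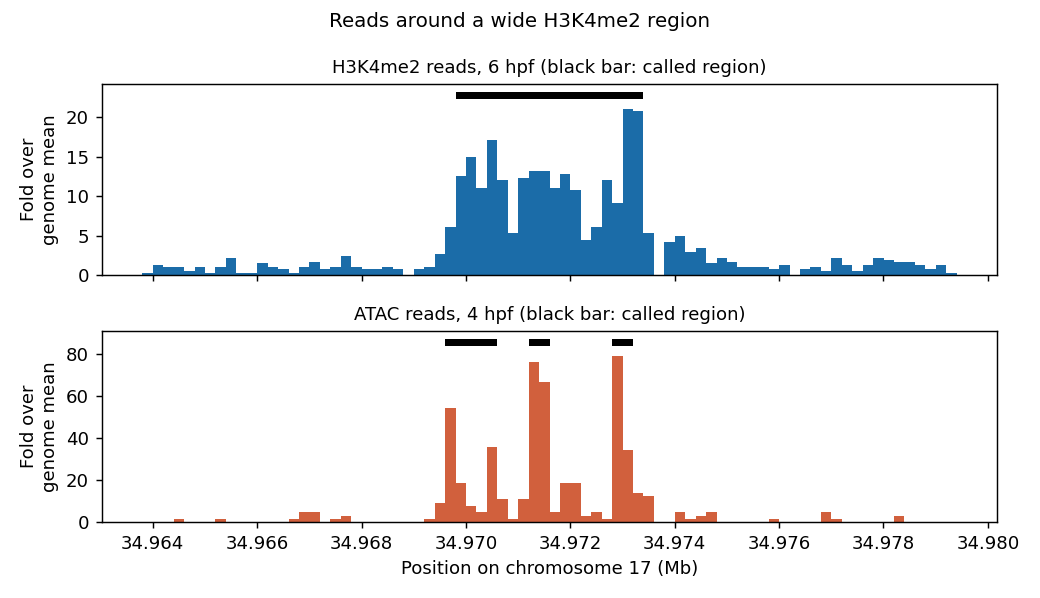
Read density in 200 bp bins (vertical axes, fold over the genome mean) along chromosome 17 around 34969801 to 34973400 (horizontal axis, Mb), for H3K4me2 above and ATAC below, with called regions as black bars. The H3K4me2 region of 3600 bp meets 3 ATAC regions.

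The strongest open sites were more varied in H3K4me2. The ATAC region with most reads lay on chromosome 7 at 7289001 to 7291200, with 460 reads, 65.1-fold the mean. It met no H3K4me2 region, yet H3K4me2 density there was 8.30-fold the mean, and it lay inside a wide H3K4me2 region, 7286201 to 7294400, when the genome-wide background alone was used. Likewise chromosome 7 at 76818801 to 76820800, with 414 reads and 64.4-fold, met no H3K4me2 region at an H3K4me2 density of 7.71-fold, and lay inside such a wide region at 76818401 to 76829800. With repeated reads kept its ATAC density was 99.7-fold. These wide regions were chosen after their values were seen. The other 8 of the 10 ATAC regions with most reads met an H3K4me2 region. Among them, chromosome 8 at 1334401 to 1336000 had the highest ATAC density, 68.1-fold, with H3K4me2 at 12.1-fold, and chromosome 21 at 2065001 to 2067400 had 45.2-fold with H3K4me2 at 2.11-fold. The 10 widest ATAC regions, 2400 to 3000 bp, all met an H3K4me2 region, and H3K4me2 density over them ran from 1.88-fold to 14.4-fold. The widest lay on chromosome 3 at 8434201 to 8437200, with ATAC at 30.8-fold and H3K4me2 at 10.96-fold.

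Chromosome 4 held fewer open sites per Mb than any of the other chromosomes. It had 21.7 ATAC regions per Mb, against 29.4 on chromosome 22 and 38.9 on chromosome 23, the lowest and highest of the other 24. It had 19.4 H3K4me2 regions per Mb, against 19.7 on chromosome 9 to 28.6 on chromosome 22. The deficit was deepest between 30 and 57 Mb, an interval chosen after the data were seen, which held 142 ATAC regions, 5.26 per Mb, and 316 H3K4me2 regions, 11.7 per Mb. From 0 to 30 Mb there were 1062 and 746, or 35.4 and 24.9 per Mb. From 57 Mb to the end there were 28.7 ATAC and 28.1 H3K4me2 regions per Mb, the first below and the second above the values from 0 to 30 Mb. The window from 21 to 24 Mb held 57 ATAC and 39 H3K4me2 regions with 88.2% of its bins holding reads. H3K4me2 regions between 30 and 57 Mb were short, with a median of 200 bp and 20 reads, against 600 bp and 98 reads from 0 to 30 Mb. Of those between 30 and 57 Mb 12.3% (8.93 to 16.5) met an ATAC region, against 52.8% (49.2 to 56.4) from 0 to 30 Mb. These shares compare regions of unlike size: over all chromosomes 17.3% of H3K4me2 regions of 200 bp met an ATAC region. Of bins between 30 and 57 Mb, 40.3% held any read, against 88.6% from 0 to 30 Mb.

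**Figure D5:**
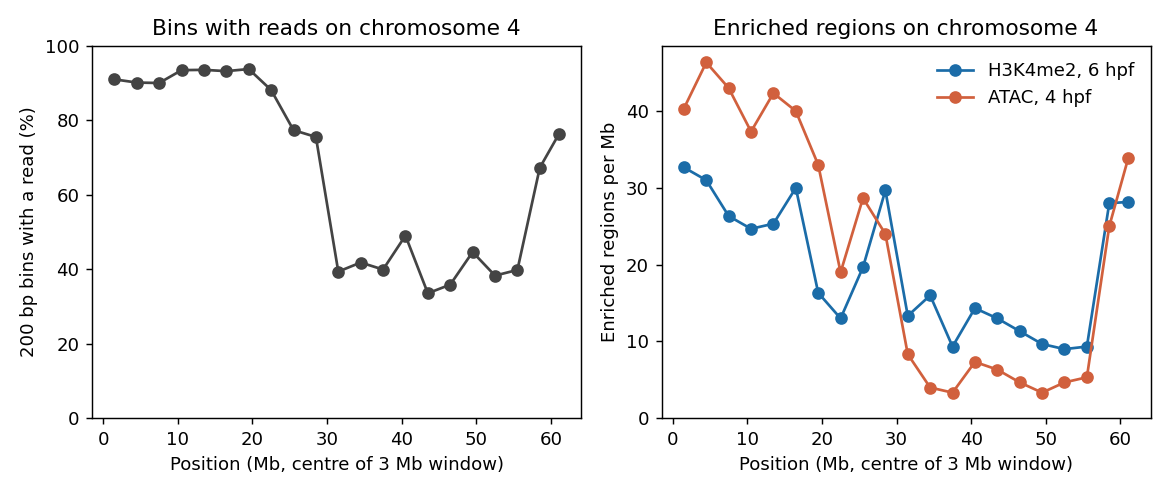
Share of 200 bp bins with a read of either library (left, percent) and enriched regions per Mb (right) along chromosome 4 in windows of 3 Mb, the last one shorter (horizontal axes, Mb), with points for windows and 1 line per library on the right. Between 30 and 57 Mb, where 40.3% of bins hold reads, regions number 11.7 per Mb for H3K4me2 and 5.26 per Mb for ATAC.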

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

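Mitochondrial reads were present in both libraries and are given here because no comparison above used them. They made up 0.340% (95% exact binomial interval 0.338 to 0.342) of the H3K4me2 reads and 9.31% (9.29 to 9.34) of the ATAC reads. The mitochondrial genome of 16596 bp carried 279 times the read density of the nuclear chromosomes in the H3K4me2 library and 8399 times in the ATAC library. Counting each position and strand once, an alternative chosen after the data were seen, gave 0.108% and 0.578%, and on so short a genome this count is limited by the number of positions.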

How the results depend on the processing

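All 30 alternative values of the shares that met and of the H3K4me2 level at ATAC regions kept their direction, with a one-sided permutation p of 0.000999, the smallest 1000 shifts can give. The share of ATAC regions ran from 21.8% (thinned H3K4me2 reads) to 43.8% (500 bp bins), that of H3K4me2 regions from 40.1% (50% of the region covered) to 65.8% (thinned), and the level from 3.92-fold to 6.31-fold. Chosen after the data were seen were shifts of 20 to 200 kb, shifts over bins with reads, reads moved 30 bp, chromosome 4 without 30 to 57 Mb, unmoved reads at ATAC summits, and some pairings of settings with other results. Counts moved by over 1.5 times in 2 cases: 15720 H3K4me2 regions from thinned reads, with fewer reads by construction, and 26971 ATAC regions at an adjusted p under 1e-05, a stricter threshold.

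The ratio of centre to flank, 1.39, stayed above 1 and was 1.42 with all reads kept and with thinned reads, 1.41 with reads moved 30 bp, 1.37 at an adjusted p under 1e-05, with the genome-wide background and at ATAC summits with unmoved reads, and 1.33 with 500 bp bins; the cause was not tested. Mitochondrial shares fell to 0.108% and 0.578% with distinct positions, by construction. The share that met in the 10% with most reads ran from 50.8% to 81.3% for ATAC regions and from 63.5% to 99.1% for H3K4me2 regions. The 32 named regions were 17 of H3K4me2 and 15 of ATAC. Thinning or moving H3K4me2 reads leaves ATAC calls as they were. Of the 17 H3K4me2 regions, 15 still met a region with thinned reads and all 17 did with reads moved 30 bp. All 32 named regions did with all reads kept, stricter adjusted p, genome-wide background and 500 bp bins. Their folds were less stable: with all reads kept 23 of the 32 moved beyond their counting intervals, and 4 rose by over 1.5 times. Depth limited the calls to bins at 3.44-fold the mean for H3K4me2 and 7.28-fold for ATAC. Other settings listed beforehand for promoters, gene lists, annotated features and promoter sequence classes were not run. No paired analysis was possible because each group held 1 library.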

Other observations

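Of the tests in this part, those of H3K4me2 depth and of distance to H3K4me2 regions were set before their results were seen, and the others were chosen after. Both kinds of region were denser near chromosome ends. In the outer 5% at each end the median over chromosomes was 30.4 H3K4me2 regions per Mb against 22.5 in the middle 90%, and it was higher at the ends in 23 of 25 chromosomes. For ATAC regions the medians were 43.6 and 34.0 per Mb, higher at the ends in 24 of 25.

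Some H3K4me2 stretches were much wider than the regions called against the local background, which were 3600 bp at most. Against the genome-wide background alone, 76 H3K4me2 regions reached 5 kb. The widest lay on chromosome 25 at 36193201 to 36209000, 15800 bp long, with H3K4me2 at 6.42-fold and ATAC at 26.4-fold the mean and 9 ATAC regions met. Others were chromosome 25 at 36161201 to 36174000, chromosome 7 at 76844001 to 76856600 and chromosome 7 at 76818401 to 76829800, the last of which contains the open site at 76818801 named above. Chromosome 25 at 28541801 to 28554200 was 12400 bp long at 5.78-fold. It met no ATAC region called against the local background, but its ATAC density was 3.81-fold the mean. What raised the reads of both libraries over these stretches was not tested, and no input was used. These regions were chosen after their values were seen.

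H3K4me2 was highest at the centre over all open sites. With unmoved reads around ATAC summits the ratio of centre to flank was still 1.37 (1.37 to 1.38), so the excess did not need the 75 bp move. In the 354 sites with an H3K4me2 region among the 1% of ATAC regions with most reads it was 0.891 (0.866 to 0.916). Whether placement of reads or of summits was the cause stays open. An unmoved read is counted at the end of a fragment whose length was not measured. How exactly summits were placed was not tested. A transposase library under the H3K4me2 label was argued against by the ratio of 0.995 at 9 bp. Recovery of open chromatin irrespective of the mark could not be told apart from H3K4me2 itself: rho corrected for counting noise was 0.471, below the bound of 0.5 set for it, but that bound was wrong because openness was measured in a library labelled 4 hpf and the mark at 6 hpf, and the input was not used here. A candidate explanation that stays open is that nucleosomes with H3K4me2 lie within or close beside these sites.

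Too few H3K4me2 reads cannot be told apart from a lack of the mark at the 29390 open sites without an H3K4me2 region: the interval of the H3K4me2 level reached the smallest callable level in 21.7% (21.2 to 22.2) of them, but depth itself sets that level, so the bound of 50% was wrong, thinning cut the share that met from 37.9% to 21.8%, and these sites averaged 1.74-fold against 1.19-fold at 2 to 3 kb. The local background hid H3K4me2 in 7.97% (7.66 to 8.28), which met a region once the genome-wide background was used, although it did so in 36.5% of the 1319 such sites among the 10% of ATAC regions with most reads. In that 10%, 837 sites, 17.7% (16.6 to 18.8), lacked an H3K4me2 region against either background, and whether some are false ATAC calls was not tested. Of the 29390 sites without an H3K4me2 region, 24.1% (23.6 to 24.6) lay within 5 kb of one. Shifts gave a mean of 19.7% and a highest of 20.7% (permutation test, one-sided p = 0.000999, the smallest 1000 shifts can give). Shifts of 20 to 200 kb and shifts over bins with reads, chosen after, gave highest shares of 21.7% and 21.6%. The local background spans the same 5 kb, so it can leave sites beside strong H3K4me2 uncalled, as in the 7.97% above. The comparison was not repeated without those sites, so it cannot tell nearness from this effect of calling. A difference between the labelled stages of 4 and 6 hpf stays open and untested.

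Chromosome 4 held few open sites between 30 and 57 Mb. Per 1000 bins with reads there were 2.61 (2.2 to 3.08) ATAC regions, below the 7.29 to 8.93 of the other 24 chromosomes, and 5.81 (5.19 to 6.49) H3K4me2 regions, within their 4.48 to 7.10. This does not decide whether sequence to which few reads map uniquely may be the cause, since bins with reads held 2.49 H3K4me2 reads there against 4.56 to 4.97 elsewhere, so that counting such bins did not correct for it. ATAC reads per 1000 H3K4me2 reads were 124 there, against 134 to 178 on the other chromosomes. Less mappable sequence and less open chromatin cannot be told apart for this interval, and no biological explanation was tested.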
